A study of Mus musculus with 4 samples.

How the data were processed

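The samples are 4 biological replicates of a single group: mouse primary T cells of strain C57BL/6NJ, activated towards the T helper 17 (Th17) fate and carrying a STARR-seq reporter library as an episome after transient transfection. Per the labels, the cells were treated for 3 days with antibodies to CD3e at 0.25 µg/mL, CD28 at 1 µg/mL, interleukin-4 at 2 µg/mL and interferon-gamma, and with interleukin-6; 30 µg of nucleic acid was the starting quantity and the size range was 200 to 400. In STARR-seq a genomic fragment sits in the transcribed part of a reporter plasmid, so that the amount of RNA carrying a fragment, relative to the plasmid DNA put in, measures how much that fragment raised its own transcription. The labels name another experiment as a possible control; its data are not analysed here.

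The measurements came from 1 table of elements on mouse build mm10, which per the file headers the authors derived from the alignments of all 4 replicates. It gives, for each element, the authors' log2 fold change, the authors' p-value and q-value, and the element length. No counts and no values per replicate were used here, so the depth of each sample is unknown, no standard deviation over replicates can be given, and every value per element is the authors' own. The aligner, the element caller and their versions are not given in the sources used here. The direction of the log2 fold change is not stated either; it was taken to be reporter RNA over input, and "higher" and "lower" elements below are those with a positive or negative value.

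The deposited table was checked before use. All 24232 elements had a length equal to end minus start plus 1, so starts count from 1, and all had bounds on a grid of 25 bp. Every q-value was under 0.01. Each deposited q-value equalled, within a relative tolerance of 1e-06, the Benjamini-Hochberg adjustment of the p-values over 114722 tests. By that reckoning 21.1% of the tested elements are in the table and 90490 elements that did not pass are not used here. Shares of higher elements are therefore shares among elements that differed from the reference level in either direction, not among all tested fragments.

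The genome sequence was GRCm38, whose chromosome lengths fit every listed element, with GENCODE mouse release M21. The 24217 elements on chromosomes were annotated, and 15 on unplaced or unlocalised contigs were left out of all tests. Each element was assigned by its centre to the nearest transcription start site (TSS) of a protein-coding gene, called promoter-proximal within 1 kb of it and distal otherwise, and given the location (coding exon, untranslated region, intron or intergenic) of its centre. GC percent, the observed over expected CpG ratio and the share of repeat-masked bases came from the sequence. Matches to 40 consensus sequences of transcription factors were searched on both strands, and each consensus reversed without complementing served as a composition control; the consensus of KLF and SP reads the same when reversed and has no such control. Elements were linked to 14 gene lists when the nearest coding TSS lay within 100 kb. Near-identical copies were found with minimap2 2.31-r1302 (k of 19, w of 10) as alignments to the chromosomes with at least 95% identity over at least 90% of the element; 589 elements, with a median of 50 bp, did not align to their own position and have no copy number.

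The groups, lists, motifs, tests and most alternatives were fixed before the data were examined. The planned test was Fisher's exact test on the number of active elements, those past a q-value of 0.05 with a positive log2 fold change. Because the table holds no elements that failed it, the fallback fixed with it was used: the difference in median log2 fold change between 2 sets of elements, with a two-sided permutation test of 100000 resamples whose smallest p is 2e-05, and Benjamini-Hochberg adjustment over the lists and over the motifs. Sets under 10 elements were not tested. The log2 fold changes fall into a negative and a positive cloud with few values near 0, so a median can jump between them. The share of higher elements, with an exact (Clopper-Pearson) binomial 95% interval that covers counting error only and Fisher's exact test, was therefore added after seeing the data. Odds ratios over GC deciles were planned for all elements and added after seeing the data for motifs in distal elements; they are Mantel-Haenszel estimates with 95% intervals and a chi-square test. Elements are not replicates, and neighbouring elements are not independent, so the p-values describe this table and not the spread between cultures.

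The median test was tested on simulated sets of 200 elements drawn from the 24217. Among 100 sets with no shift it called 8, with a shift of 0.5 it called 39, and with a shift of 1 it called 49. In sets made to hold 60% higher elements the median test called 79 of 100 and Fisher's exact test 91; at 70% each called 100, and at 50% they called 6 and 2. These simulations used fewer resamples than the tests and drew elements singly. The tested gene lists hold 17 to 124 elements grouped by gene, so these rates do not carry over to them.

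The elements named in the text follow a fixed rule: the 8 highest and the 8 lowest log2 fold changes, not all of which are given; for Th17 genes the element of smallest p per gene, for at most 15 genes; and for every other list the 2 elements of smallest p. The 18 motifs described singly were chosen after their values were seen, as were elements said to be so. Alternatives covered the fold change and q thresholds, merging of elements within 1 kb, the TSS windows of 500 bp and 2 kb, linking distances of 20 kb and 500 kb, distal elements only, the central 200 bp of each element, GC and length strata, leaving out chromosome 2, which had the most elements, leaving out elements with near-identical copies, and 1 value per gene. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, numba 0.67.0, pysam 0.24.0 and matplotlib 3.10.9.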

Results

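Reporter activity of genomic fragments was measured by STARR-seq in mouse Th17 cells, the interleukin-17-producing lineage of CD4 T helper cells. The 4 biological replicates form 1 group, and the comparison the design implies is that of reporter RNA with the input library, element by element. The authors' deposited table combines the replicates and lists 24232 elements of 50 to 2125 bp (median 575 bp) on mm10; the fold change and q-value of each element below are the authors' own. The files do not state the direction of the fold change, which is taken here as reporter RNA over input, so higher means more RNA than input; were it the reverse, higher and lower would change places in every comparison below. Sequencing depth per replicate is unknown here, and no value carries an error between replicates.

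Elements above and below the reference level were about equally frequent. The authors' deposited table lists 11972 elements with a positive log2 fold change and 12260 with a negative one, each at a q-value under 0.01. On the chromosomes, the higher elements had a median log2 fold change of 1.47 and the lower ones of -1.33. Higher elements were shorter, with a median of 450 bp against 700 bp, and poorer in GC, with a median of 46.8% against 63.2%.

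The highest value in the authors' deposited table was 8.91, for an intergenic element of 900 bp on chromosome 17 (21477701 to 21478600), 10848 bp from the TSS of the zinc finger gene Zfp53. It was followed by elements nearest G530012D18Rik (8.77), Gm2237 (8.65), Gm3636 (7.67), Unc93a2 (7.49), Tmpo (7.45), Samd9l (7.40) and Bmper (7.37). Near-identical sequence elsewhere on the chromosomes makes 5 of these 8 uncertain in position: the elements nearest Gm2237 and Gm3636 had 30 and 29 other copies, those nearest G530012D18Rik 3, Unc93a2 2 and Samd9l 1. The element nearest Tmpo spans 50 bp and could not be checked for copies.

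The lowest value was -8.37, for an element of 1050 bp centred on a coding exon of chromosome 10 (43021001 to 43022050), with Scml4 as the nearest coding TSS at 119052 bp. Also among the 8 lowest in the authors' deposited table were elements nearest Asphd2 (-7.74), Neu2, a sialidase gene (-7.70), Fign (-7.54), Sipa1l1 (-7.51) and Sorcs1 (-7.40). The elements of Asphd2, Neu2 and Fign lay within 388 bp of the TSS, and none of those named had a near-identical copy. The element nearest Sorcs1 lay 992660 bp from its TSS.

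**Figure D1:**
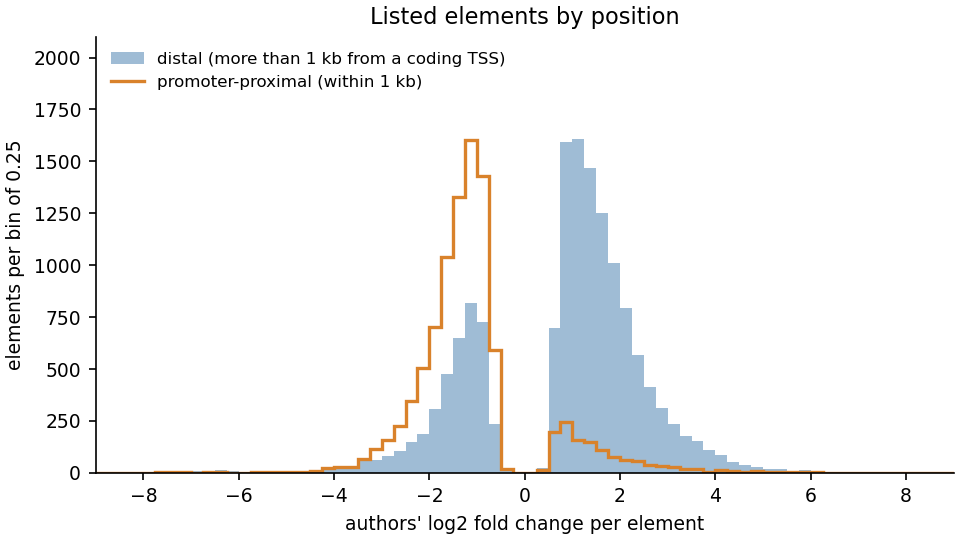
Number of listed elements (vertical axis, bins of 0.25) by the authors' log2 fold change (horizontal axis), for 14709 distal elements (filled) and 9508 promoter-proximal elements (line). Few elements lie near 0, and the proximal elements sit mostly on the negative side, with a median of -1.22 against 1.16.

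Elements at promoters were mostly lower and those away from promoters mostly higher. Of 9508 promoter-proximal elements 1261 were higher (13.3%, exact binomial 95% interval 12.6% to 14.0%), against 10700 of 14709 distal elements (72.7%, 72.0% to 73.5%). Their median log2 fold changes were -1.22 and 1.16, a difference of -2.38 (permutation p = 2e-05, the smallest that 100000 resamples can give). The share of higher elements was 11.6% within 250 bp of a coding TSS, 23.2% at 500 bp to 1 kb, 63.0% at 2 to 5 kb, 76.4% at 20 to 100 kb and 94.4% beyond 500 kb. By location, 14.0% of elements centred on untranslated regions and 12.6% of those on coding exons were higher, against 58.6% in introns and 60.5% between genes. Among distal elements, split this way after the data were seen, the shares were 64.6% of 260 on untranslated regions, 23.9% on coding exons, 73.4% in introns and 75.3% between genes.

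Promoter-proximal elements were also richer in GC, with a median of 64.7% against 47.6%. Over GC deciles the odds ratio for a promoter-proximal element to be higher was 0.508 (95% interval 0.460 to 0.562), whereas without strata it was 0.0573 (0.0534 to 0.0614). In the sixth GC decile 37.5% of promoter-proximal and 52.2% of distal elements were higher.

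**Figure D2:**
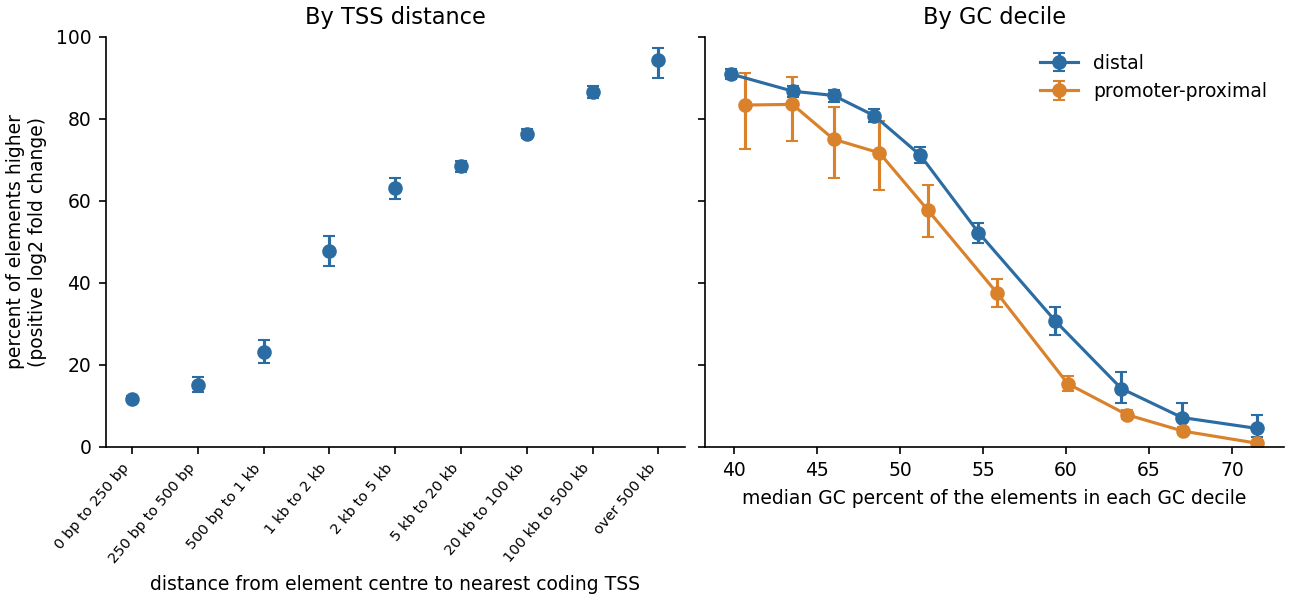
Percent of listed elements with a positive log2 fold change (vertical axis), by distance from the element centre to the nearest coding TSS (left) and by the median GC percent of each GC decile, for distal and promoter-proximal elements (right). Bars are exact binomial 95% intervals; the share climbs from 11.6% within 250 bp to 94.4% beyond 500 kb and falls with GC in both positions, apart from the lowest 2 deciles of proximal elements (83.3% and 83.5%).

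Elements near Th17 genes were more often higher than elements near other genes. Of 115 elements linked to 31 of the 32 Th17 genes, 74 were higher (64.3%, exact binomial 95% interval 54.9% to 73.1%), against 45.6% of the other linked elements. Their median log2 fold change was 0.93, which is 1.70 above that of other linked elements (permutation p = 0.00392, adjusted p = 0.0127 over 13 tested lists). This call ended with GC strata (odds ratio 1.27, 0.769 to 2.09, chi-square adjusted p = 0.757) and with distal elements alone, where the difference was -0.058 (permutation, adjusted p = 0.741), and with 1 value per gene (1.24, 31 genes, permutation adjusted p = 0.0742). It ended as well with an absolute log2 fold change of at least 1 (2.26, 72 elements, permutation adjusted p = 0.129) and with a q under 0.001 (0.48, 78 elements, permutation adjusted p = 0.148). Over all 11 alternatives the adjusted p, from exact, permutation or chi-square tests, lay between 0.000179 and 0.757.

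The element with the smallest p, below called the strongest, was higher for each of the 15 Th17 genes named here. The element so chosen was higher in 5037 of all 11512 other genes (43.8%), against 45.7% of all linked elements. The former is a share of genes and the latter of elements. The pair therefore cannot show whether choosing by smallest p favours higher elements. A very low smallest p went with higher elements. The chosen element was higher in 2215 of the 3164 other genes with a smallest p as low as in these 15. In the authors' deposited table their log2 fold changes were, by gene, Tnfsf8 (3.31), Nfkbiz (3.25), the lineage-modulating transcription factor gene Maf (3.06), Gpr65 (3.06), Stat3 (2.60), which transduces interleukin-6 signals, the cytokine gene Il10 (2.56), Hif1a (2.29), Fosl2 (2.22), Bhlhe40 (2.00), the STAT3 feedback inhibitor gene Socs3 (1.92), Ahr (1.91), the chemokine receptor gene Ccr6 (1.61), Irf4 (1.33), Il17a (1.19) and Il17f (1.12). The Tnfsf8 element lies in an intron on chromosome 4 (63842076 to 63842725, q = 2.44e-19) and the Maf element between genes on chromosome 8 (115739776 to 115740250, q = 1.3e-16). Most elements of Socs3 (3 of 4) and of Irf4 (5 of 6) were lower. Among the remaining 16 Th17 genes with an element, the strongest was higher for 9 and lower for 7, and over all 31 genes 11 had higher elements alone, 5 lower ones alone and 15 both. Il17re had no linked element.

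At the neighbouring cytokine genes Il17a and Il17f on chromosome 1, all 5 elements of the authors' deposited table were higher, from 0.97 to 1.22. They comprise an element at the Il17a promoter (20730651 to 20731000, 0.97), another 9808 bp from the Il17a TSS (20740476 to 20740950, 1.19) and 1 near the Il17f TSS (20791451 to 20792025, 1.01). The 5 had a median GC of 47.7%, and in the GC decile around that value 80.3% of all elements were higher. All 5 lay under 1.47, the median of higher elements. Other Th17 loci were picked after their values were seen. Il23r, the interleukin-23 receptor gene, had 3 higher elements up to 1.40, and Il21 had 3 up to 1.04.

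**Figure D3:**
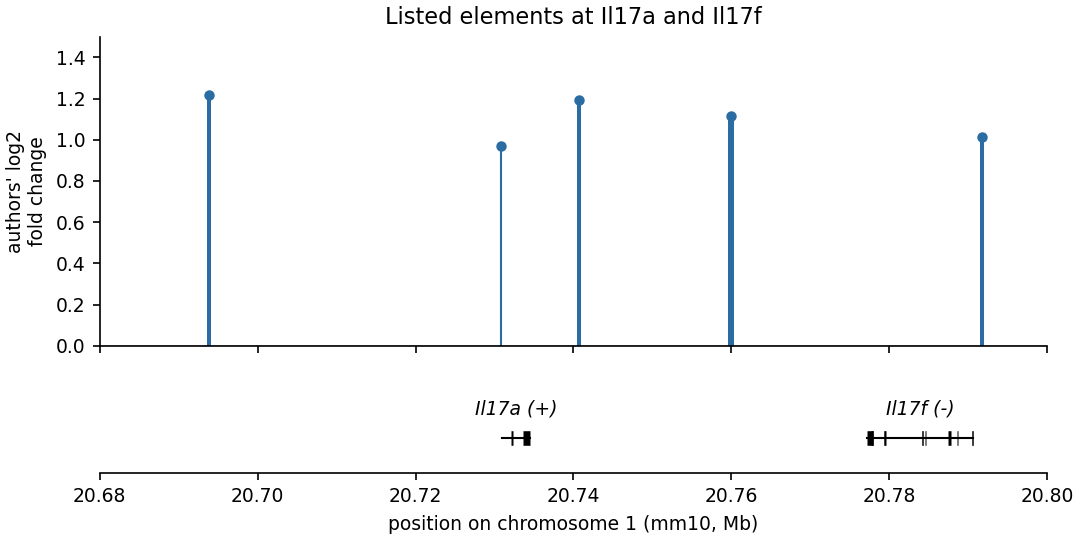
Listed elements at Il17a and Il17f, by position on chromosome 1 (mm10, horizontal axis in Mb) and the authors' log2 fold change (vertical axis), with gene models and strands below. All 5 elements are above 0, between 0.97 and 1.22; bar widths are to scale.

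Interferon-stimulated genes had the most one-sided elements of the 13 tested lists. Of 37 elements linked to 25 of these genes 32 were higher (86.5%, exact binomial 95% interval 71.2% to 95.5%), with a median log2 fold change of 1.88 (difference 2.65, permutation p = 2e-05, adjusted p = 0.00026). Their strongest elements in the authors' deposited table were those 145 bp from the TSS of Isg15, a ubiquitin-like antiviral gene (4.18), and 78 bp from that of Ifih1, which encodes an RNA sensor (3.80). Over GC deciles the odds ratio was 3.99 (1.59 to 10.0, chi-square adjusted p = 0.00395), and the call ended with the 13 distal elements alone (difference 0.31, permutation, adjusted p = 0.561). The adjusted p over all alternatives for this list and for activation genes ran from 2.77e-06 (Fisher's exact test on the share) to 0.561.

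Elements of T cell activation and immediate early genes were higher in 85 of 124 cases (68.5%, 59.6% to 76.6%), with a difference in medians of 1.68 (permutation p = 0.0039, adjusted p = 0.0127). Over GC deciles their odds ratio was 2.42 (1.51 to 3.89, chi-square adjusted p = 0.000175), while among distal elements the difference was -0.12 (permutation, adjusted p = 0.561). The call also ended with 1 value per gene (difference 1.22, 28 genes, permutation adjusted p = 0.0742) and without chromosome 2 (1.62, 112 elements, permutation adjusted p = 0.0642). It ended with an absolute log2 fold change of at least 1 (2.25, 75 elements, permutation adjusted p = 0.129) and with a q under 0.001 (0.43, 91 elements, permutation adjusted p = 0.163). The strongest were an intronic element of the nuclear receptor gene Nr4a2 (2.62) and an element 2230 bp from the TSS of the AP-1 subunit gene Junb (2.76) in the authors' deposited table. Most elements of Nr4a2 (2 of 3) were lower. Th1 genes had 44 higher elements of 59 (74.6%, 61.6% to 85.0%), led by Runx3 (2.78, with 3 of its 5 elements lower) and Stat4 (4.01). Their difference in medians was 1.95 (permutation p = 0.00106, adjusted p = 0.00689). Strata of GC ended that call (odds ratio 2.03, 0.932 to 4.43, chi-square adjusted p = 0.223), as did each of distal elements alone (difference 0.10, permutation, adjusted p = 0.690, the largest of its alternatives, whose smallest was 4.04e-05 by Fisher's exact test), 1 value per gene (difference 1.29, 17 genes, permutation adjusted p = 0.115) and an absolute log2 fold change of at least 1 (2.47, 44 elements, 0.0672).

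The remaining lists did not pass the median test. Treg genes had 40 higher elements of 55 (72.7%, permutation adjusted p = 0.103), led by Nt5e (3.59) and the promoter of Ctla4 (2.80), an inhibitory receptor gene. That share is above the 64.3% of the Th17 list, and Treg genes passed by Fisher's exact test on it (adjusted p = 0.000179) and with links within 20 kb (permutation adjusted p = 0.0348). IL-6 and STAT3 target genes had 47 of 75 (62.7%, permutation adjusted p = 0.0578), with the kinase gene Pim1 (2.63) and Junb in front, and passed over GC deciles (odds ratio 2.30, 1.24 to 4.25, chi-square adjusted p = 0.0143), with adjusted p from 0.00657 to 0.744 over its alternatives. Of its 20 genes, 7 are also in the Th17 list, 2 in the activation list and 1 in the T cell identity list. Its result is therefore not independent of theirs. T cell identity and TCR signalling genes had 71 of 117 (60.7%, permutation adjusted p = 0.171). In front were Lef1 (2.83, with 4 of its 6 elements lower) and the interleukin-7 receptor gene Il7r (2.66). This list passed by Fisher's exact test on the share (adjusted p = 0.00315) and with links within 20 kb (permutation adjusted p = 0.0259), but not over GC deciles (odds ratio 0.998). Th2 genes had 23 of 44 (52.3%, permutation adjusted p = 0.370), with Ccr4 (2.66) and Il1rl1 (2.00).

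Among lists of general and other-cell-type genes, 26 of 54 elements were higher for cell cycle genes (48.1%) and 14 of 42 for ribosomal and translation housekeeping genes (33.3%). The shares were 13 of 22 for myeloid genes (59.1%), 8 of 17 for B cell genes (47.1%) and 11 of 28 for neuronal genes (39.3%), and permutation adjusted p-values of these lists lay between 0.209 and 0.914. With links within 20 kb the myeloid list, of another cell type, passed too (difference 1.98, 16 elements, permutation adjusted p = 0.0457). Their strongest elements in the authors' deposited table were those of Rpl3 (3.73) and Eef1a1 (2.08), Ebf1 (2.32) and Pou2af1 (1.98), Gad2 (1.81) and Neurod1 (2.29). Ccne2, a cyclin gene, held both a higher element 14966 bp away (4.43) and a lower one 241 bp from its TSS (-3.45). The myeloid receptor gene Fcgr3 had elements of 3.56, with 2 near-identical copies, and 4.98. Liver genes had 2 elements, at Fga (1.70) and Apoa1 (-1.02), and were not tested.

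The Th17 list was set against the other T helper lists directly, without shared genes. Elements of Th17 genes differed from those of Th1 genes by -0.25 in the median (permutation p = 0.0272, adjusted p = 0.0815), from those of Th2 genes by 0.18 (p = 0.207, adjusted 0.310) and from those of Treg genes by 0.0068 (0.903 for both). None of the 3 adjusted p-values from these permutation tests was under 0.05.

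**Figure D4:**
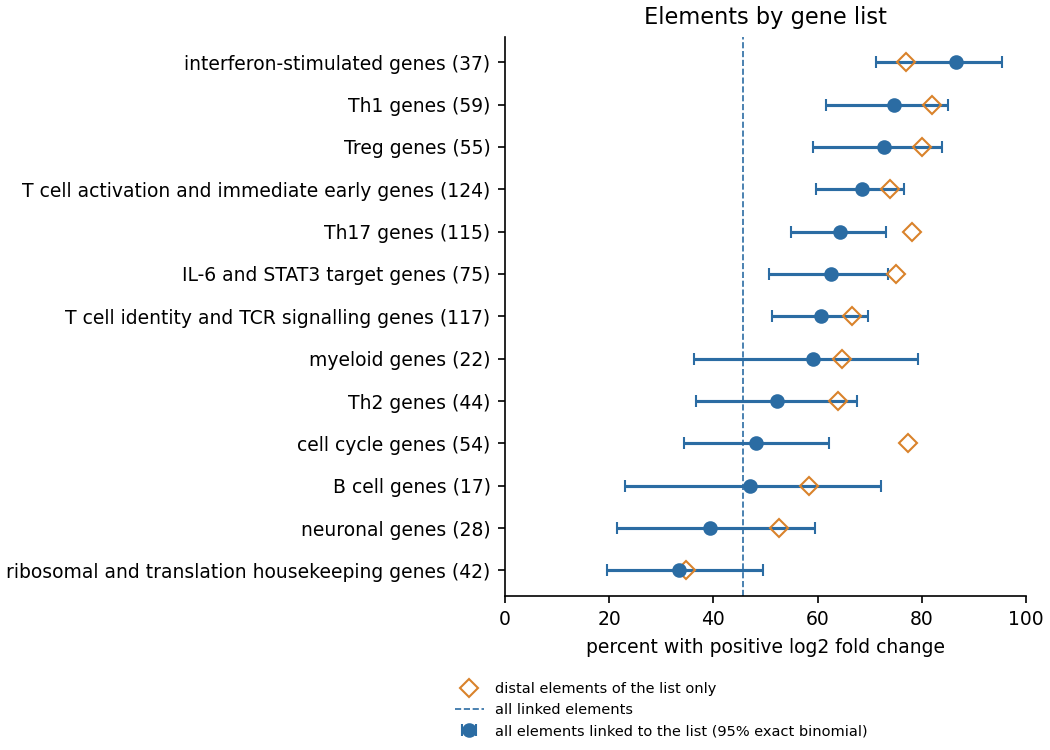
Percent of elements with a positive log2 fold change (horizontal axis) by the list of the nearest gene within 100 kb (vertical axis, number of elements in brackets). Dots are all linked elements with exact binomial 95% intervals, and diamonds are the distal ones alone. The dashed line is the 45.7% of all 22068 linked elements, promoter-proximal ones included, so it is no reference for the diamonds. Of all distal elements, linked or not, 72.7% were higher. Interferon-stimulated genes reach 86.5% by the dots.

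Recognition sequences of AP-1, CREB and ATF, IRF, NF-kB and STAT factors went with higher elements. AP-1, the family of FOS, JUN and BATF, had a match in 6391 elements, of which 80.1% were higher; among distal elements it was 87.9% with a match and 63.8% without. Over GC deciles of distal elements the odds ratio was 3.12 (95% interval 2.83 to 3.45) for AP-1, 2.74 (2.30 to 3.25) for IRF sites and 2.47 (1.88 to 3.24) for NF-kB. It was 1.65 (1.43 to 1.90) for STAT sites and 1.37 (1.19 to 1.59) for NFAT. Each of these 5 passed the Mantel-Haenszel chi-square test after adjustment.

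The share of higher distal elements went up with the number of AP-1 matches, from 63.8% of 9247 without a match to 86.6% of 4280 with 1, 92.0% of 989 with 2 and 95.3% of 193 with 3 or more. Composite sites for BATF with IRF4, a pair central to Th17 cells, were rare. Of distal elements with the spaced composite 94.0% of 134 were higher, and with the adjacent composite 95.7% of 186. Their odds ratios over GC deciles, against all distal elements without the composite, were 4.64 (2.11 to 10.2) and 5.06 (2.52 to 10.2). Among distal elements with both an AP-1 and an IRF match, 93.0% of 618 were higher. Whether a composite adds to separate matches was not tested. CREB and ATF sites had an odds ratio of 5.22 (3.18 to 8.56), with 89.1% of 230 distal elements higher. Distal elements without a match were higher in 72.5%. Over all elements, promoters included and without strata, 50.8% with a CREB and ATF match were higher. Their difference in medians did not pass (permutation adjusted p = 0.537). Of the 360 promoter-proximal elements with a match 26.4% were higher. SMAD palindromes had an odds ratio of 3.52 (1.73 to 7.17) on 117 distal elements.

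CTCF sites, bound by the insulator protein, went with lower elements. Among 418 distal elements with a CTCF match 98 were higher (23.4%, exact binomial 95% interval 19.5% to 27.8%), against 74.2% of those without, and the odds ratio over GC deciles was 0.163 (0.127 to 0.209). KLF and SP sites (0.700), EGR sites (0.522), T-box sites (0.700), GATA sites (0.771) and the E-box CACGTG (0.678) had odds ratios below 1 as well, with no 95% interval reaching above 0.899. For EGR and CACGTG the reversed sequence gave nearly the same values, 0.548 and 0.705. Over all elements, promoters included and without strata, GATA sites went the other way, with 59.0% higher elements among those with a match. T-box sites then had a difference in medians of 0.082 that did not pass (permutation adjusted p = 0.827).

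RUNX and ETS sites, both frequent in T cell enhancers, did not stand apart at equal GC. Their odds ratios in distal elements were 0.991 (0.866 to 1.13) and 0.941 (0.712 to 1.24). Over all elements, promoters included and without strata, 70.3% of those with RUNX and 19.9% of those with ETS matches were higher. Among distal elements without strata 55.3% of 309 with an ETS match were higher, against 73.1% of those without. YY1 sites reached 1.91 (1.47 to 2.49), and their reversed sequence 1.96 (1.00 to 3.83).

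By the difference in medians over all elements, 18 of 39 tested motifs were higher and 14 lower in the permutation test at an adjusted p under 0.05. The reversed sequences gave 13 and 10 of 35. In distal elements over GC deciles the counts were 15 higher and 9 lower of 37 motifs, against 2 and 3 of 34 reversed sequences. The p53 consensus matched 6 elements and was not tested.

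**Figure D5:**
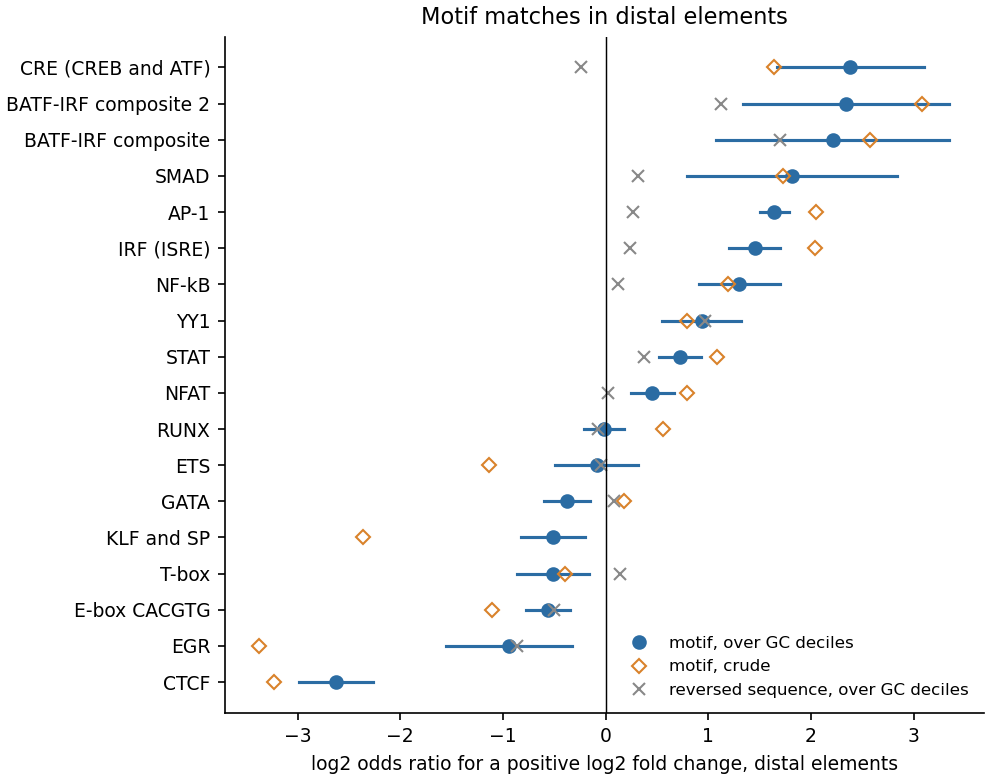
Log2 odds ratio for a distal element to have a positive log2 fold change when it holds a motif (horizontal axis), for 18 motifs (vertical axis). Dots with 95% interval bars are over GC deciles, diamonds are crude, and crosses are the reversed sequence over GC deciles; AP-1, IRF and NF-kB dots lie above 0 and CTCF below.

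Fold changes fell with GC content and CpG content, and with element length except among the shortest elements. Across the 24217 elements, which are not independent replicates, Spearman's rho with the log2 fold change was -0.653 for GC percent, -0.521 for the observed over expected CpG ratio and -0.339 for length (permutation p = 1e-05 each, the smallest possible, before and after adjustment over 3 relations). By length, 33.5% of 1379 elements of 50 to 100 bp were higher, 76.6% at 125 to 300 bp, 65.3% at 325 to 600 bp and 14.3% above 1 kb. In the lowest GC decile 90.7% of elements were higher and in the highest 1.20%. Among distal elements rho was -0.371 for GC percent, -0.137 for CpG and -0.171 for length.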

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

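All 15 elements outside the assembled chromosomes were left out of the tests above, since the annotation used did not cover them. Of these elements, on 7 unplaced or unlocalised contigs, 11 had a positive log2 fold change in the authors' deposited table. Their median was 1.03, with values from -2.18 to 2.60, and the largest q-value was 0.00716. They drew attention because they carry signal in data that none of the comparisons use; no technical or biological explanation was tested for them.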

How the results depend on the processing

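Alternatives with a q under 0.001, near-identical copies left out, length strata, the share of higher elements, 1 value per gene, and distal elements over GC deciles were chosen after seeing the data. Input counts, the ratio of output to input counts, leaving out a replicate, and a q under 0.1 could not be run, since the table used holds no counts, no replicate values and no q above 0.01; a q under 0.05 or 0.01 keeps every listed element. No paired analysis was possible because there is 1 group. Promoter-proximal elements stayed lower under all 11 alternatives, and the 3 composition correlations kept their sign and their side of 0.05 under all 4. With a q under 0.001, which kept 17302 elements, the lower elements dropped to 7888 and were fewer than the higher ones.

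The call for Th17 genes ended with an absolute log2 fold change of at least 1 (difference 2.26, 72 elements left), a q under 0.001 (0.48), GC strata (log2 odds ratio 0.34) and 1 value per gene (1.24), and the difference was -0.058 in distal elements. The number of lists called higher, 4, became 1 with the fold change minimum and 1 with 1 value per gene (interferon-stimulated genes in both), 2 with a q under 0.001 (with Th1), 7 by the share of higher elements (Treg, T cell identity, and IL-6 and STAT3 targets added), 8 within 20 kb (myeloid genes added to those), 3 over GC deciles (activation and interferon-stimulated genes, and IL-6 and STAT3 targets) and 0 in distal elements. No list was called lower under any of these. Motifs called lower went from 14 to 9 over GC deciles, with the central 200 bp only, and in distal elements over GC deciles.

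Uncalled differences changed sign in several lists. In distal elements they were -0.23 for Th2, -0.11 for Treg, -0.27 for T cell identity, -0.31 for B cell and -0.31 for myeloid genes, -0.051 for IL-6 and STAT3 targets, and -0.12 for activation genes, whose main difference had been called. Over GC deciles log2 odds ratios were -0.17 for Th2, -0.0030 for T cell identity, -0.79 for B cell and 0.14 for neuronal genes. The rest were 0.15 for ribosomal genes and -0.12 for B cell genes within 20 kb, -0.30 for B cell genes with the fold change minimum, and 0.21 for neuronal genes with 1 value per gene.

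Over GC deciles, in distal elements, and in distal elements over GC deciles, signs turned for RUNX (-0.032, -0.014, -0.014), GATA (-0.36, -0.066, -0.37), T-box (-0.45, -0.16, -0.51) and YY1 (1.02, 0.21, 0.93). T-box also turned with the fold change minimum (-0.0032), merging (-1.01) and without chromosome 2 (-0.085), YY1 with the central 200 bp (1.36), and CREB and ATF with a q under 0.001 (-0.0096). For the 21 motifs not named, 151 of 203 alternatives gave the same call and 27 turned the sign. GC strata lessen the GC trend by construction but leave what varies within a stratum; the cause of the changes was not tested. Depth is unknown here, so what it limits was not assessed.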

Other observations

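All tests in this and the next paragraph were chosen after the values were seen. Promoters of interferon-stimulated genes stood apart from other promoters. Of their 24 promoter-proximal elements 22 were higher (91.7%), against 13.1% of other promoter-proximal elements, with an odds ratio over GC deciles of 14.1 (95% interval 3.26 to 60.8). Xaf1, Isg15, Oasl1, Irf9 and Oas3 were among the genes, with single elements of 4.41, 4.18, 4.18, 3.49 and 3.47 in the authors' deposited table. Promoters of T cell activation and immediate early genes were higher in 14 of 28 cases, at an odds ratio of 13.3 (5.27 to 33.8), while Th17 promoters were higher in 6 of 28, at 0.872 (0.290 to 2.62). AP-1, IRF, and CREB and ATF matches went with higher elements at promoters too, with odds ratios over GC deciles of 2.57 (2.13 to 3.10), 3.14 (2.51 to 3.93) and 3.57 (2.67 to 4.76). Most promoter-proximal elements with these matches were still lower, with 33.9%, 39.8% and 26.4% higher. Among the other motifs examined there, NF-kB (2.89), YY1 (2.71) and STAT sites (1.64) also went with higher elements. CTCF had an odds ratio of 0.579, and ETS, NFY and NRF1 had 1.13, 1.04 and 0.894.

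Among distal elements, 59.5% were higher with neither an AP-1 nor an IRF match, 87.3% with AP-1 alone, 89.4% with IRF alone and 93.0% with both. Median log2 fold changes of these groups were 0.93, 1.24, 1.66 and 1.48. Distal elements centred on coding exons were higher in 23.9% of 443 cases against 73.4% in introns, at an odds ratio over GC deciles of 0.453 (0.333 to 0.617). Distal elements with at least 50% repeat-masked bases were higher in 90.3% of 1047 cases, at an odds ratio of 2.54 (2.05 to 3.15) over GC deciles.

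The tests of reads shared between copies and of an interferon response, below, were chosen only after the result was seen. Elements with near-identical copies elsewhere were almost all higher. Of 439 such elements 437 had a positive log2 fold change, with a median of 3.23 against -0.63 for the 23189 with none, and 56 of the 100 highest elements had a copy against 0 of the 100 lowest. GC content and matches to AP-1, IRF and NF-kB are argued against as whole causes. The odds ratios stayed at 187 (95% interval 35.0 to 995) over GC deciles and 369 (87.0 to 1566) over strata of these matches. Both estimates rest on the 2 copied elements that were lower, and no other motifs were used as strata. Listed elements may be copies of each other, which was not checked. These intervals and the permutation p below treat them as independent. Whether reads shared between copies contribute was not decided. Among the 439 the log2 fold change went up with the number of copies (Spearman's rho 0.261, permutation p = 1e-05, the smallest possible). That rise cannot tell shared reads from other properties of copied sequence, since such reads could enter RNA and input alike. How the authors treated such reads is not given in the sources used here. Beyond those motifs no biological explanation was tested.

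Promoter-proximal elements were mostly lower, as reported above. GC content as the whole cause would bring the odds ratio to 1, and over 50 GC bins it was 0.550 (0.496 to 0.608); over deciles of length it was 0.0832 (0.0771 to 0.0898). The value over GC bins lay much nearer 1 than the crude value of 0.0573, so a large part of the crude difference went along with GC. Strata cannot tell GC itself from other properties of promoters that go with GC. A remaining GC trend within bins could add to the difference that is left. An effect of the reporter's own promoter or of amplification was not tested, and no biological explanation was tested.

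At promoters 39.8% of elements with an IRF match were higher. Distal elements with an IRF match were mostly higher (90.6%). In distal elements neither GC content (odds ratio 2.74, 2.30 to 3.25, over GC deciles) nor AP-1 sites beside the match (3.84, 3.13 to 4.71, in the 9247 elements without an AP-1 match) accounts for this as the whole cause. An interferon response of the cells to transfected DNA stays open and undecided: the odds ratio of elements nearest interferon-stimulated genes (3.99, 1.59 to 10.0, 37 elements) is the list result that raised the question, so it is no evidence for that response. IRF4 activity in Th17 cells could act at the same sites, which was not tested either. RNA levels of the cells' own genes, which could part these, were not analysed here. The biological explanation was not tested, as the design has 1 group.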
